A study of Arabidopsis thaliana with 6 samples.

How the data were processed

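RNA from unopened flower buds of Arabidopsis thaliana was measured on 6 single-colour Affymetrix arrays with biotin-labelled target. All plants carried anac019-1, a T-DNA insertion line of the NAC transcription factor gene ANAC019 in the Col-0 background, and all had been under drought. The labels name 3 groups, buds taken on day 3, day 4 and day 5 of the treatment, with 2 replicates each. Group and replicate number were taken from the sample titles. Nothing in the labels says that the replicates came from separate pots or plantings, so the p-values measure the spread between these samples, which may be technical.

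The values are log2 probe set summaries that the authors deposited. The submitters' processing notes name RMA and the R package affy, without versions. RMA corrects the background of each array, equalises the distribution of probe intensities across arrays and summarises each probe set by median polish. Whether these 6 arrays were normalised alone or with others is not given in the sources used here. The values ran from 2.3 to 14.5, and the array medians lay between 6.97 and 7.03. RMA compresses the changes of dim probe sets, so a fold change from a value near the lower end understates the change. It also forces the arrays to a common distribution, so every change reported is relative to the other transcripts on the array. There are no detection calls and no scan dates in the data used here. Array number, 2 per day, limits the precision.

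The table held 22810 probe sets. The 64 Affymetrix control probe sets were left out of the tests, which left 22746. Probe sets were named through the platform annotation, whose symbols were updated by gene identifier through a RefSeq gene table of the TAIR10.1 assembly. That annotation gave 1 gene for 13513 probe sets, several genes for 503 and none for 8730. Of the probe sets with 1 gene, 13436 matched the gene table and the others kept the annotation's own name. They stood for 13355 genes. No gene was named from a probe set with several genes, and a probe set that the annotation does not list is unnamed here, which does not mean that it lacks a gene. ANAC019 itself is among the genes with no named probe set, so the mutated gene was not analysed here and could not serve as a check of the labels. The same holds for NAC055, RD26, DREB2A, RD29A, RD29B, NCED3, P5CS1, HSP101, MS1, MYB21, DUO1 and AG, which had been chosen beforehand for naming.

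Day means were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with the default prior and all 6 arrays in a single model of 3 group means. The model had 3 residual degrees of freedom per probe set, and the fitted prior added 4.69. Contrasts were day 4 against day 3, day 5 against day 4, day 5 against day 3, and the difference between the daily steps. A moderated F test covered the 3 days together. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a comparison, and the threshold was an adjusted p of 0.05. Reported changes are differences of log2 day means with the moderated standard error of limma.

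Before the data were examined, 27 gene lists were written down for this tissue and treatment, with 805 entries, and the tests, the alternatives and the rule for naming genes were fixed. Members were matched by locus and checked by symbol or synonym, and 4 without a locus were taken by symbol. For 29 entries the gene table gave no symbol and the locus was kept, 5 entries whose locus and symbol differed were left out, and 4 more that had no locus were left out too. Because many well-studied genes are unnamed here, only 132 entries were measured, and 13 lists had at least 5 measured genes. Those were tested with the limma function camera at a preset correlation of 0.01, with the brightest probe set standing for each gene and all 13355 genes as background. An estimated correlation and the limma function fry, which asks whether the genes of a list move on balance in the same direction, were the alternatives.

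The naming rule took, for each comparison, up to 10 of the largest rises and 10 of the largest falls among probe sets with 1 gene past the threshold whose arrays did not overlap between the days. It added up to 4 members with the smallest p of each list that passed its test or held a gene past the threshold, at most 2 members of other lists, and the gene AMS. MGH3, named for day 5 against day 3, lies outside this rule. A gene without a symbol is named by its locus.

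Other alternatives were a filter on probe sets with a mean under 5, probe sets of 1 gene only, a trended and robust prior, cyclic loess, centring on the array median, array weights, the replicate number as a block, a 2-fold requirement, the 4 arrays of the days compared, and leaving out each array in turn. Centring on the poly-A spike-in controls was added after seeing the data. It assumes that equal amounts of these controls were added to every sample, which is not recorded here. Where leaving out an array leaves 1 for its day, the lone array is assumed to vary like the other days' arrays.

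The code was tested on simulated data for 22746 probe sets, with variances drawn from the fitted prior and 67, 67 and 66 probe sets changed by 0.5, 1 and 2 on the log2 scale. For day 4 against day 3, 8.96% of changes of 0.5 were recovered, 76.1% of changes of 1 and 100% of changes of 2. For day 5 against day 4 the shares were 2.99%, 74.6% and 100%. For day 5 against day 3 none of the changes of 0.5, 73.1% of those of 1 and 97% of those of 2 were recovered. In the data far more probe sets were called, 5020 for day 5 against day 4 and 6548 for day 5 against day 3. The adjusted threshold eases as more probe sets change, so the simulated shares do not describe recovery in these comparisons. With no change simulated, 0 probe sets were called in any comparison. A simulated list of 8 genes raised by 0.5 was called with the preset correlation at an adjusted p of 9.27e-10, and with the estimated correlation it was missed at an adjusted p of 0.0864. The simulated genes varied independently of each other. In the data the estimated correlation reached 0.636 for the ABA list and 0.688 for the tapetum list. The simulation therefore cannot tell which setting suits lists with such correlations. It does show that the estimated setting can miss a simulated shift among independent genes. Lists with a low or negative estimated correlation weakened too. For heat shock (0.0112) from day 3 to day 4, the unadjusted camera p went from 0.000398 to 0.0387. For senescence (-0.0826) from day 4 to day 5 it went from 0.00168 to 0.048. A call lost under this setting therefore does not by itself show that correlation among the genes undid it.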

Results

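The series measured the flower transcriptome of the anac019-1 mutant under severe drought. Plants were watered until just after bolting, at 24 days of growth, and water was then withheld. After about 80 hours, counted as day 3, soil moisture was near 35% of what the soil could hold, and it was kept there. Buds were taken on days 3, 4 and 5, from plants 28, 29 and 30 days after germination, with 2 arrays per day. Wild-type and well-watered buds were not analysed here, so drought duration and plant age move together in every comparison, and nothing below separates the mutation from the treatment.

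Day 5 arrays stood apart from those of days 3 and 4, while arrays of days 3 and 4 resembled each other about as much as replicates did. Pearson's r across all 22746 tested probe sets was 0.9937 between the day 3 replicates, 0.9963 on day 4 and 0.9939 on day 5. Between days it was 0.9919 to 0.9948 for days 3 and 4, 0.974 to 0.9826 for days 4 and 5, and 0.9638 to 0.9731 for days 3 and 5. These correlations are across probe sets, which are not independent replicates. The first principal component held 73.2% of the variance and ordered the days. The mean 3′ minus 5′ difference of the actin, GAPDH and ubiquitin control probe sets was 2.23 in day 3 replicate 1, against 1.62 to 1.81 in the other arrays. Probe sets of the poly-A spike-in controls averaged 6.45 ± 0.09 on day 3, 6.55 ± 0.12 on day 4 and 6.95 ± 0.12 on day 5 (SD, n = 2 per day). Such controls are meant to be added to the RNA before labelling, and the amount added is not recorded here. The 25S ribosomal RNA probe set read 11.62 ± 0.24, 11.89 ± 0.48 and 12.96 ± 0.21 on the same days (SD, n = 2).

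From day 3 to day 4, AT2G37870 had the largest rise, from 6.81 ± 0.30 to 9.94 ± 0.56 (SD, n = 2), a change of 3.13 ± 0.25 (SE) on the log2 scale, or 8.78-fold (limma adjusted p = 0.00413; not past the threshold without day 3 replicate 2). HIS1-3 (AT2G18050), a linker histone variant known to be induced by drought and abscisic acid (ABA), rose 5.29-fold, with a standard error of 0.33 on the log2 scale (adjusted p = 0.0337), a call lost with a trended and robust prior, with array weights, and without either day 3 array or either day 5 array. GI (AT1G22770), the clock-associated gene GIGANTEA, rose 5.27-fold, from 5.85 ± 0.16 to 8.25 ± 0.17 (SD, n = 2; adjusted p = 0.00246). The late embryogenesis abundant gene LEA4-5 (AT5G06760) rose by 1.78 ± 0.26 (adjusted p = 0.0394), and did not pass when any 1 array was left out. The other 6 leading rises were AT4G33550 (2.64), AT3G53980 (2.18), AT2G21820 (2.04), AT1G16850 (1.90), AT5G52390 (1.87) and AT1G04770 (1.85), as log2 changes. The call of AT2G21820 was lost without either day 3 array or either day 5 array. That of AT1G16850 was lost without either day 3 array or day 4 replicate 1, and those of AT3G53980 and AT1G04770 without day 4 replicate 1. AT4G33550 and AT5G52390 kept theirs.

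The largest falls from day 3 to day 4 were those of AT5G44020, which changed by -2.49 ± 0.21 on the log2 scale (adjusted p = 0.0049; lost without either day 4 array), and AT2G45180, by -2.31 ± 0.17 (adjusted p = 0.00275). AT1G65490, AT2G30930, AT5G03350, AT4G17470 and AT2G41090 fell too, with log2 changes from -1.97 to -1.34. The call of AT4G17470 was lost without day 3 replicate 1, either day 4 array or either day 5 array. TBL45, of the trichome birefringence-like family, changed by -1.27 and CSLA03, a cellulose synthase-like A gene, by -1.20, beside AT1G09750 at -1.22.

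Of the 5 measured genes of the ABA and dehydration list, 1 rose, none fell and 4 did not pass between day 3 and day 4; adjusted over the list alone, 3 rose. COR15A (AT2G42540), which encodes a chloroplast stromal protective protein, rose by 0.97 ± 0.13 (adjusted p = 0.0335), a call lost when any 1 array was left out. Its relative COR15B differed by 0.50 (adjusted p = 0.149) and the dehydrin LTI30 (AT3G50970) by 2.34 (adjusted p = 0.147), with day 3 arrays at 3.99 and 5.90 for LTI30. The list as a whole was shifted up against other genes (camera adjusted p = 5.69e-06), a call that was lost with adjusted p = 0.356 under an estimated correlation. None of the 8 measured heat shock genes passed over all genes, and 3 did when adjusted over the list alone. AT5G51440 differed by 0.52 and ATHSP22.0 by 0.49, both small heat shock proteins near the lower end of the scale. The list was shifted up with adjusted p = 0.00258, lost with adjusted p = 0.356 under an estimated correlation, and 0.114 without day 3 replicate 2; its median of 0.24 was 0.13 with arrays centred on the poly-A spike-in controls. Of 9 auxin genes only GH3.3, which conjugates auxin to amino acids, passed, with a change of -0.74 ± 0.11 (adjusted p = 0.0394) that was likewise lost without any 1 array. The auxin list and the other 10 tested lists were not called. AMS, a tapetum regulator, differed by 0.14 (adjusted p = 0.9).

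In all, 114 of 22746 probe sets passed between day 3 and day 4, 61 higher and 53 lower, and 77 of them changed at least 2-fold. This count fell whichever array was left out. Leaving out a day 5 array changes no value of days 3 and 4. Either omission is the same check, of the spread that the day 5 replicates lend to the model. It was 17 without day 3 replicate 1, 15 without day 3 replicate 2, 17 without day 4 replicate 1, 23 without day 4 replicate 2 and 58 without either day 5 array, and of the 22 genes named above that passed, between 8 and 16 still did. AT1G09750, AT1G65490, AT2G41090, AT5G03350, CSLA03 and TBL45 were lost without any 1 of the 4 arrays of these days. With arrays centred on the poly-A spike-in controls, an alternative added after seeing the data, 205 passed and 32.7% of them were higher, against 53.5%.

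**Figure D1:**
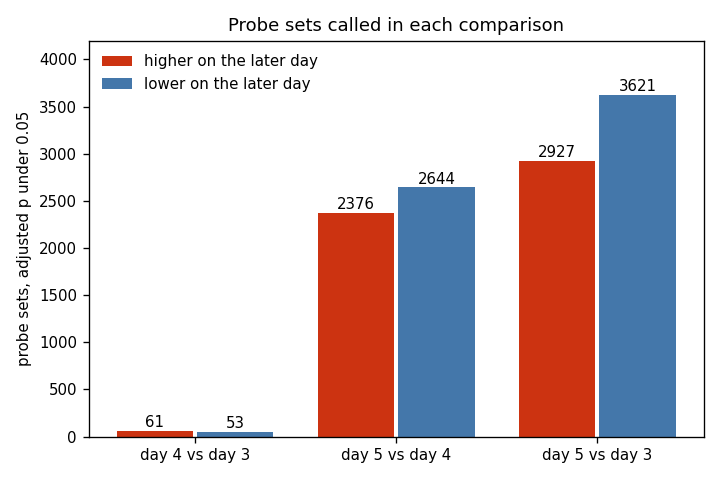
Number of probe sets past an adjusted p of 0.05 (vertical axis) in each comparison of days, with those higher on the later day in red and those lower in blue. The step from day 3 to day 4 had 61 higher and 53 lower, and the step from day 4 to day 5 had 2376 higher and 2644 lower.

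From day 4 to day 5, AT3G17520, a late embryogenesis abundant protein gene, had the largest rise, from 4.12 and 4.08 on the day 4 arrays to a mean of 9.63 ± 0.10 (SD, n = 2), a change of 5.53 ± 0.12 (SE), or 46.2-fold (limma adjusted p = 2.92e-06). HIS1-3 rose by a further 5.12 ± 0.33, or 34.7-fold (adjusted p = 0.000154). AT3G15670, another late embryogenesis abundant gene, rose by 4.89, and AT1G22890, AT2G21820, AT1G49500, AT3G15450, AT5G45310, AT2G20670 and AT5G66780 by 4.59 to 3.78. BCAT4 (AT3G19710), an aminotransferase of methionine chain elongation for glucosinolates, had the largest fall, a log2 change of -3.02 ± 0.29 (adjusted p = 0.00079). XTH32, a xyloglucan endotransglucosylase/hydrolase gene of the cell wall, fell 3.99-fold.

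The other 8 of the 10 largest falls were AT4G16270, AT4G11190, AT4G29980, AT5G24820, AT3G07450, AT5G55620, AT5G41890 and AT5G03350, with log2 changes between -2.86 and -1.91. In some of them the day 5 arrays differed widely: AT4G29980 read 7.72 in replicate 1 and 5.93 in replicate 2, and AT3G07450 read 9.41 and 7.78.

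Of 10 measured genes of late pollen and the pollen tube, 5 rose and none fell between day 4 and day 5; adjusted over the list alone, 7 rose. AGL66 and AGL104, MADS-box factors of pollen maturation, rose by 0.97 and 1.06, the pollen tube receptor kinase gene ANX1 by 0.89, and the pollen actin gene ACT12 by 0.91. The median change was 0.90, and the list was shifted up (camera adjusted p = 8.15e-05; adjusted p = 0.524 with an estimated correlation). Of 10 early anther and tapetum genes, 2 fell, none rose and 8 did not pass; adjusted over the list alone, 4 fell and 1 rose. SHT (AT2G19070), a hydroxycinnamoyl transferase of the tapetum, changed by -1.83 ± 0.26 (adjusted p = 0.00338) and AT1G06170 by -0.59 (adjusted p = 0.0176), the latter lost without either day 4 array or day 5 replicate 2. AMS differed by -0.60 without passing (adjusted p = 0.0704). The list median was -0.42 with a camera adjusted p of 0.0343, and the adjusted p was 0.567 with an estimated correlation. It was 0.0615 without either day 3 array, 0.0808 without day 4 replicate 1, 0.212 without day 5 replicate 2 and 0.0712 with the filter on low values. On day 5 all 10 of these genes read lower in replicate 2 than in replicate 1, by a median of -0.46.

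The lists of nutrient remobilisation and of sugar transport genes were each shifted up as a whole at the same step. Of 7 senescence genes, 3 rose and none fell; adjusted over the list alone, 4 rose. GAMMA-VPE (AT4G32940), a vacuolar processing protease, rose by 1.58 ± 0.16 (adjusted p = 0.000941), the autophagy gene ATG8H rose from 7.43 to 8.64, and APG8A rose by 0.53 on the log2 scale. The camera adjusted p was 0.0109, and with an estimated correlation the adjusted p was 0.524. None of 11 sugar transport genes passed by itself, over all genes or adjusted over the list alone, while their median change was 0.57 and the list's adjusted p was 0.0198 (adjusted p = 0.524 with an estimated correlation, 0.212 without day 5 replicate 2). SWEET4 differed by 0.57 (adjusted p = 0.0515) and the invertase gene AT1G62660 by 0.49 (adjusted p = 0.0526). Sugar transporters did not rise as a class. Of the 14 measured genes named SWEET, tested as a family after seeing the data, 0 rose, 2 fell and 12 did not pass (camera adjusted p = 0.522). With arrays centred on the poly-A spike-in controls the median changes were 0.11 for senescence, against 0.51, and 0.17 for sugar transport, and those of late pollen and of the tapetum list were 0.50 and -0.82.

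In lists that were not called or had under 5 measured genes, single genes passed. WES1 (AT4G27260), an auxin-conjugating GH3 enzyme, rose by 2.66 ± 0.16 (adjusted p = 0.000101), the auxin-induced homeobox gene HAT2 by 1.48 and GH3.3 by 0.45, 3 of 9 auxin genes with none falling and a camera adjusted p of 0.0533. The gibberellin receptor genes GID1B and GID1C rose by 1.44 and 1.27, and GID1A by 0.68, a call lost without day 4 replicate 1, without either day 5 array and with centring on the poly-A spike-in controls, while the gibberellin signalling F-box gene SLY1 changed by -0.40. JMT, the jasmonate methyltransferase gene, changed by -0.72, which was lost without either day 4 array or day 5 replicate 2. The zinc finger gene STZ (AT1G27730) rose by 1.48 from 4.05, and the calmodulin-like gene CML38 by 0.58. GI rose by a further 1.07 ± 0.14 (adjusted p = 0.00218).

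Of 4 cell cycle genes 3 fell: PRL, a subunit of the replicative helicase, with a log2 change of -1.05, and the Aurora kinase genes AUR1 and AUR2 with -0.47 and -0.52, both lost without any 1 of the 4 arrays of these days. In the photosynthesis list 2 of 6 fell, SBPASE of the Calvin cycle (-0.50) and the photosystem I gene PSAN (-0.63), and the list was not called (adjusted p = 0.222). In the flavonoid list 2 of 7 fell, the flavonol glycosyltransferase genes UGT78D1 (-1.14) and UGT78D3 (-0.70), with a list adjusted p of 0.222. The wax ester synthase gene WSD1 changed by -0.69. Members of the ABA and dehydration list split: LTI30 rose by 3.03 and the dehydrin gene COR47 by 0.97, while COR15B changed by -1.25 (3 rose when adjusted over the list alone; list adjusted p = 0.518). In the heat shock list HSA32 rose by 0.43 and AT5G48570 and AT5G51440 changed by -0.45 and -0.49 (list adjusted p = 0.65). These 3 calls were lost without any 1 of the 4 arrays, that of HSA32 also with probe sets of 1 gene only and with a trended and robust prior, and the other two with cyclic loess. In the gynoecium list ALC, a fruit patterning factor, was the only 1 of 8 to pass, with a rise of 0.74. In the meiosis list 1 of 7 fell, and 0 when adjusted over the list alone, and none of the 5 ribosomal protein genes or the 7 floral identity genes passed. In the floral identity and gynoecium lists the median change was -0.04 and -0.02, while the mean lay above 0. None of the 4 reference genes passed, and their median change was -0.11.

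Between day 4 and day 5, 5020 probe sets passed, 2376 higher and 2644 lower, and 1045 changed at least 2-fold. The balance of directions depended on the setting: 660 of the 2-fold changes were higher and 385 lower, cyclic loess gave 2859 higher and 2180 lower, and 55.4% were higher without day 4 replicate 1 or without day 5 replicate 2 and 58.3% without day 4 replicate 2. The count was 2099 without day 4 replicate 1, 1366 without day 4 replicate 2 and 2146 without day 5 replicate 2. Of the 55 genes named for this step that passed, 36 still did without day 4 replicate 1, 32 without day 4 replicate 2, 44 without day 5 replicate 1 and 39 without day 5 replicate 2. Beside those given above, the calls of GH3.3, SLY1, PSAN and APG8A were lost in each of these cases, and those of SBPASE and SLY1 with cyclic loess. SBPASE, UGT78D3 and COR47 were lost without either day 4 array or day 5 replicate 2, CML38 without either day 4 array or day 5 replicate 1, and WSD1 without replicate 2 of either day. AT5G24820, AT3G07450 and AT4G29980 were lost without either day 4 array, AT3G07450 and AT4G29980 also with a trended and robust prior, and ACT12, ALC, ATG8H and LTI30 without day 4 replicate 2. With arrays centred on the poly-A spike-in controls instead, 11929 probe sets passed and only 7.69% of them were higher, since the median change of all probe sets is then -0.44; the directions above are therefore relative to the other transcripts on the array.

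**Figure D2:**
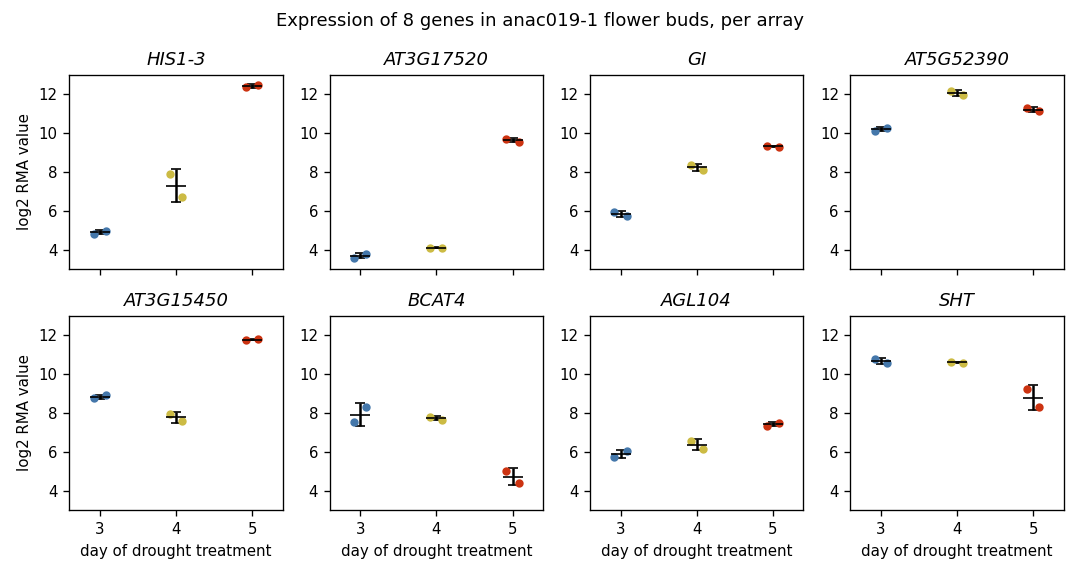
Log2 RMA values (vertical axis) of 8 genes against the day of drought treatment (horizontal axis). Coloured points are the 2 arrays of a day, bars are the mean ± SD; HIS1-3 rose at both steps, AT3G17520 rose between day 4 and day 5, and the day 5 replicates of SHT lie apart.

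**Figure D3:**
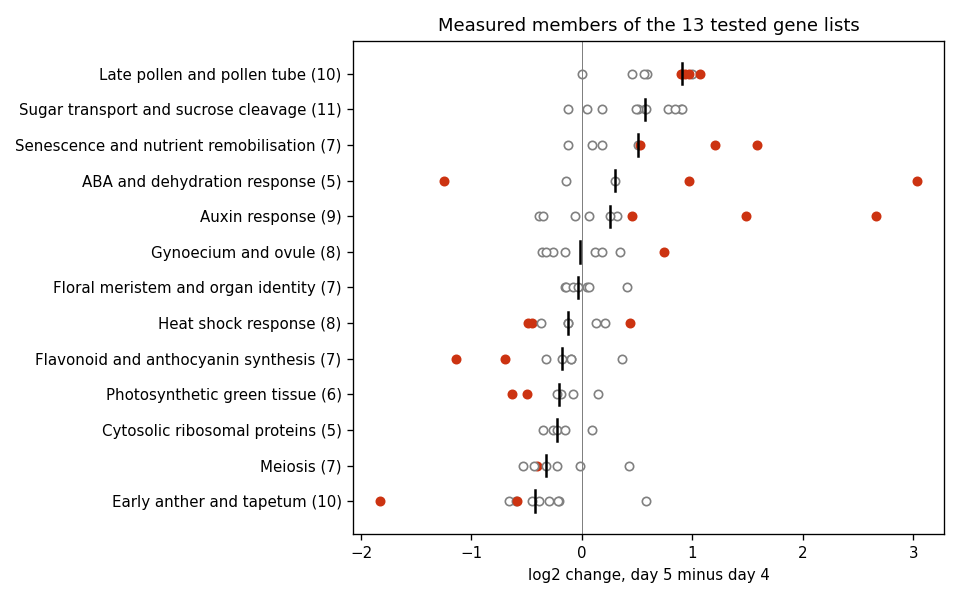
Log2 change from day 4 to day 5 (horizontal axis) of each measured member of the 13 tested gene lists, with the number of measured genes in brackets. Filled points passed an adjusted p of 0.05 over all probe sets, open points did not, and black bars are list medians, which ran from -0.42 for early anther and tapetum to 0.90 for late pollen and pollen tube.

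Over the whole interval from day 3 to day 5, HIS1-3 had the largest rise. It went from 4.90 ± 0.11 to 12.42 ± 0.09 (SD, n = 2), a change of 7.52 ± 0.33 (SE), or 183.8-fold (limma adjusted p = 1.62e-05). AT2G21820 rose by 6.41, AT3G17520 by 5.93, AT5G66780 by 5.91 and AT3G15670 by 5.68. The dehydrin gene LTI30 rose by 5.38 ± 0.52 (adjusted p = 0.000451), and the late embryogenesis abundant genes LEA4-5 and LEA18 by 4.83 and 4.62. AT1G49500 and AT5G45310 rose by 4.48 and 4.34. The largest fall was that of AT5G03350, a log2 change of -3.43 ± 0.17 (adjusted p = 2.63e-05), ahead of AT4G11190 (-3.38), BCAT4 (-3.21) and AT2G41090 (-3.07). AT4G16270, AT4G29980, AT5G62730, AT5G44020, AT5G55620 and AT1G09750 fell as well, with changes between -2.82 and -2.41.

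All 5 measured ABA and dehydration genes changed between day 3 and day 5, and 4 of them rose, also when adjusted over the list alone. COR47 rose by 1.33 and COR15A by 0.82, while COR15B changed by -0.75. The list was called (camera adjusted p = 0.0412), with adjusted p = 0.558 under an estimated correlation, 0.0663 without day 5 replicate 2 and 0.0762 with the filter on low values. Of 10 late pollen genes 7 rose and none fell, over all genes and over the list alone. AGL104 rose by 1.53 ± 0.17, MGH3, a histone H3 variant of the male gamete that was chosen after its values were seen, by 1.55, ACT12 by 1.13 and AGL66 by 0.98 (list adjusted p = 0.000322; adjusted p = 0.558 with an estimated correlation). In the senescence list 3 of 7 rose, 4 when adjusted over the list alone, led by GAMMA-VPE at 2.18 ± 0.16, with ATG8H at 1.14 and APG8A at 0.76 (list adjusted p = 0.00575; adjusted p = 0.558 with an estimated correlation). In the sugar transport list 3 of 11 rose, 4 when adjusted over the list alone: SWEET4 by 1.48, SWEET13 by 1.87 and AtVEX1 by 1.69, the last not past the threshold without either day 5 array or with a trended and robust prior (list adjusted p = 0.00288; adjusted p = 0.558 with an estimated correlation). Of all 14 measured genes named SWEET, 2 rose and 2 fell over these days (camera adjusted p = 0.461, tested as a family after seeing the data). With arrays centred on the poly-A spike-in controls the list medians were 0.32 for ABA, 0.43 for late pollen, 0.01 for senescence and 0.15 for sugar transport, against 0.82, 0.93, 0.51 and 0.65.

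In the lists that camera did not call between day 3 and day 5, photosynthesis genes fell in 3 of 6 cases (3 fell and 1 rose when adjusted over the list alone). SBPASE had a log2 change of -0.89, RCA, the Rubisco activase, of -0.74 and PSAN of -0.67. By fry this list was called down (adjusted p = 0.0242). The PSAN call was lost without day 5 replicate 2. UGT78D1 changed by -1.40 and the helicase gene PRL by -1.41. In the gynoecium list 3 of 8 rose and 2 fell, also over the list alone, with ALC rising by 1.15 and NGA1, a B3-domain factor of style development, changing by -0.77. STZ rose by 1.61, NDB2, a mitochondrial alternative NADH dehydrogenase gene, by 0.77, and GI by 3.47 ± 0.14. In the auxin list 2 of 9 rose and 2 fell, 3 when adjusted over the list alone, with a median change of -0.10 and a mean of 0.33. WES1 rose by 2.92 and HAT2 by 1.42, while the auxin synthesis genes YUC4 and YUC6 changed by -0.64 and -0.49. The YUC4 call was lost without day 3 replicate 1 or day 5 replicate 2, and the YUC6 call with cyclic loess, with array weights and without any 1 array other than day 5 replicate 2. The gibberellin receptor gene GID1B rose by 1.47. The heat shock genes AT2G29500 and HSA32 rose by 0.69 and 0.62, the former not past the threshold without day 5 replicate 1. SHT changed by -1.89, and AMS differed by -0.45 (adjusted p = 0.136). In all, 6548 probe sets passed, 2927 higher and 3621 lower, and 1702 changed at least 2-fold, 997 higher and 705 lower. Cyclic loess gave 3508 higher and 3026 lower. Without day 5 replicate 2 the count was 3894, and with centring on the poly-A spike-in controls it was 16041, of which 6.87% were higher.

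The moderated F test of any difference over the 3 days passed for 5718 probe sets, and for 2615 without day 5 replicate 2 and 3769 without day 4 replicate 2. A direct test of whether the later step differed from the earlier step passed for 440 probe sets, in 321 with the later step more upward and in 119 with it more downward. Of these, 292 rose between day 4 and day 5 with no call between day 3 and day 4, and 106 fell in that way. A further 18 fell and then rose, and 6 rose and then fell. AT1G22890 differed most between steps, by 5.17 on the log2 scale (limma adjusted p = 0.000115), then AT3G17520 by 5.12 and AT3G15450, which went from 8.84 to 7.77 to 11.77, by 5.06. AT5G61590, listed as the wax synthesis repressor DEWAX, differed by 3.79. In the other direction AT5G52390 rose to 12.06 on day 4 and fell to 11.21 on day 5, a difference of -2.72 ± 0.23 (adjusted p = 0.00223). The call of AT5G52390 was lost without day 4 replicate 1. The ABA-list gene COR15B differed by -1.75 (adjusted p = 0.00834), a call lost without either day 4 array. GI differed by -1.33 (adjusted p = 0.0379), its earlier step being the larger. The count of differing steps rested on both day 4 arrays, since it was 43 without replicate 1 and 34 without replicate 2 of that day; it was 204 without day 3 replicate 1 and 165 without day 5 replicate 2. Of the 28 genes named for this test, 20 still passed without day 3 replicate 1, 25 without day 3 replicate 2, 10 without day 4 replicate 1, 13 without day 4 replicate 2, 23 without day 5 replicate 1 and 19 without day 5 replicate 2; GI was lost in each case. With centring on the poly-A spike-in controls 784 probe sets passed, 28.1% of them more upward, against 73%.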

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

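The tests of explanations in this part were chosen after the results were seen; the test of differing steps was planned.

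Effects of the 2 daily steps differed by the direct test of their difference for 440 probe sets. Among the named genes, the later step was more upward for AT1G22890 (5.17 on the log2 scale), AT3G17520 (5.12), AT3G15450 (5.06), AT4G27450 (4.64), AT2G20670 (4.33), AT3G15670 (4.11), AT3G20340 (4.08), AT1G49500 (3.95), AT5G61590 (3.79) and AT5G45310 (3.60). The same held for the list members WES1 (2.403), HAT2 (1.55), GID1C (1.53), GID1B (1.40), STZ (1.35) and GH3.3 (1.19). It was more downward for BCAT4 (-2.83), AT4G33550 (-2.76), AT5G52390 (-2.72), AT2G37870 (-2.50), AT1G04770 (-2.09), AT3G53980 (-2.03), AT4G20420 (-1.98), AT1G61930 (-1.97), AT4G11190 (-1.91), EXPA15 (-1.89), COR15B (-1.75) and GI (-1.33). Of these 28 genes, 10 still passed without day 4 replicate 1, and 13 without day 4 replicate 2.

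Far more probe sets passed from day 4 to day 5 than from day 3 to day 4, 5020 against 114. The tables argue against a single deviating day 5 array, since the lower of the counts without a day 5 array was 2146. A shift or intensity trend left in the deposited values is argued against as the whole cause. Cyclic loess, which exchanged part of the calls, still gave 5039 against 126. Centring on the array median gave 5062 against 114, but the medians already lay between 6.97 and 7.03, so it could move little. Neither correction can show a distortion that the common distribution of RMA hides. Centred on the poly-A spike-in controls, the counts were 11929 against 205. RNA degradation on day 5 cannot be told apart: the 3′ minus 5′ difference of control probe sets, 1.809 and 1.731 there, lay above both day 4 arrays (1.677 and 1.665) and below the 2.23 of day 3 replicate 1. Drought duration, plant age and an unrecorded batch of preparation or scanning stay open as untested explanations, because each day is its own group.

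Control probe sets outside the tests carried a signal of their own. The poly-A spike-in controls were 0.503 higher on day 5 than on day 3 and the 25S ribosomal RNA probe set was 1.35 higher. The hybridization controls did not share the rise of the ribosomal RNA probe set. Its excess over them on day 5 against days 3 and 4 was 1.14 (SE 0.21). For the poly-A controls the excess was 0.383 (SE 0.17) and the 95% bound was 0.538, so a rise shared with the hybridization controls cannot be told apart. Brighter hybridization of whole arrays cannot be judged from these values, because RMA had already equalised the arrays. A smaller share of messenger RNA in the total RNA of day 5 buds may account for both, and the day 5 minus day 3 difference of 0.503 leaves this open. The amount spiked in, if any, and the batch are not recorded, and each day is its own group.

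All 10 of the largest falls from day 4 to day 5 were deeper in day 5 replicate 2 than in replicate 1, by a median of -0.834, and the tapetum list was lower there by a median of -0.457, in 10 of 10 genes. Fewer anthers at the tapetum stage in that collection cannot be told apart from a stronger response of these genes to drought, which was not tested, because 1 array stands against 1 and the genes of the list move together (estimated correlation 0.688), so that their number adds little. Poorer RNA in replicate 2 cannot be told apart either, since its 3′ minus 5′ difference was -0.078 relative to replicate 1, within the SD of 0.31 among the replicates of days 3 and 4. A replicate 2 further along the same change (a factor of 1.21 over all genes, first principal component 58.84 against 45.7, median gaps of 0.39, 0.247 and 0.24 in the senescence, sugar transport and late pollen lists) predicts a median gap of -0.387 for the 10 falls, of which 8 were deeper than predicted, and -0.0786 for the tapetum list, of which 10 of 10 genes were deeper, by a median of -0.378. These values cannot decide it. The 10 falls were chosen for their depth from the mean of the same day 5 arrays, which favours genes with a low value in either replicate. The replicates are single arrays, and the list's genes are no independent count.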

How the results depend on the processing

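Centring on the poly-A spike-in controls was chosen after seeing the data, and the other alternatives were planned. With it the median change of all probe sets became -0.109, -0.439 and -0.545 for day 4 against day 3, day 5 against day 4 and day 5 against day 3, and the counts became 205, 11929 and 16041, with 784 differing steps and 14406 in the F test. Of the named genes that had passed, none turned direction under it, and 0 of 22, 7 of 55, 6 of 52 and 3 of 28 lost their calls in the 3 comparisons and the test of differing steps. From day 4 to day 5 these were ALC, APG8A, CML38, COR47, GH3.3, GID1A and HSA32, and from day 3 to day 5 ANX1, APG8A, AT2G29500, COR15A, HSA32 and NDB2. Medians of tested lists turned with it from 0.302 to -0.0959 (ABA) and from 0.258 to -0.14 (auxin) for day 5 against day 4, and from 0.196 to -0.306 (heat shock) for day 5 against day 3. For day 4 against day 3 those of meiosis, late pollen, gynoecium and senescence turned, from values between 0.0291 and 0.0948 to values between -0.0754 and -0.00979. Testing probe sets of 1 gene only, which tests fewer, gave 46, 2548, 3439, 161 and 2931 for the same 5 counts in order. A 2-fold requirement left 1045 and 1702 in the later comparisons and 1817 in the F test. Array weights gave 829 differing steps, and the 4 arrays of days 3 and 4 alone gave 58 for their comparison; the cause of the former was not tested. The filter on low values, the trended and robust prior, cyclic loess and centring on the array median kept every count of probe sets within 1.5 times. Leaving out each array in turn gave 15 to 58 for day 4 against day 3, 1366 to 5427 for day 5 against day 4, 3894 to 5375 for day 5 against day 3, 34 to 408 differing steps and 2615 to 5606 in the F test.

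Of the gene lists, 2, 4 and 4 were called in the 3 comparisons. With an estimated correlation the numbers were 0, 0 and 0. That setting also missed the simulated list of independent genes (camera adjusted p = 0.0864). By fry 0 lists passed for day 4 against day 3, 3 for day 5 against day 4 and 8 for day 5 against day 3. Of the 3 only senescence was also called by camera: auxin (adjusted p = 0.00441) and meiosis (0.0223) passed, while late pollen (0.0598), tapetum (0.142) and sugar transport (0.142) did not. The 8 held the 4 lists that camera called and auxin, shifted up (fry adjusted p = 0.0123). They also held photosynthesis (0.0242), floral identity (0.0262) and flavonoid (0.0415), all shifted down. With the filter on low values, which left 8 lists to test, 1 was called for day 4 against day 3 and 2 for day 5 against day 3. Leaving out each array gave 1 to 5, 2 to 5 and 3 to 5 lists. With the replicate number as a block the counts of probe sets were 123, 5827, 7333, 546 and 6533, and 2, 4 and 4 lists were called. The deviations of same-numbered arrays correlated at 0.0987 for days 3 and 4, 0.376 for days 4 and 5 and 0.145 for days 3 and 5, and with 2 numbers this pairing rests on the number alone.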

Other observations

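Gene families sharing a symbol stem were tested after seeing the data, so all tests here were chosen late, 48 families with at least 5 measured genes. The ATG family of autophagy genes, mostly forms of the ubiquitin-like protein ATG8 that coats autophagosomes, was shifted up from day 4 to day 5. Of its 8 genes 7 rose, and ATG3 differed by 0.22 without passing. ATG8E rose by 1.59, ATG8F by 1.05 and ATG8B by 0.81 on the log2 scale. ATG8H rose from 7.43 to 8.64, and it is also a member of the senescence list, so this result partly repeats that one. The family median was 0.68 (camera adjusted p = 3.35e-05, and adjusted p = 0.659 with an estimated correlation). The family tests were not repeated with arrays left out. From day 3 to day 5 the median was 0.98 and 7 of 8 rose (adjusted p = 0.000111; adjusted p = 0.562 with an estimated correlation). With arrays centred on the poly-A spike-in controls the medians were 0.28 and 0.48. From day 3 to day 4 none of the 8 passed.

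Nuclear genes named OTP, which encode pentatricopeptide repeat proteins that process organelle transcripts, were lower on day 5. From day 3 to day 5, 6 of 8 fell, with a median log2 change of -0.52 (camera adjusted p = 0.0499; adjusted p = 0.562 with an estimated correlation). OTP84 changed by -1.02 and OTP43 by -0.60. Among 69 genes encoded in the plastid genome, 11 fell and none rose over the same days, a share of falls like that of all probe sets (3621 of 22746), with a median of -0.38 (camera adjusted p = 0.0499; adjusted p = 0.694 with an estimated correlation). From day 3 to day 4 none of these 69 passed, and their median was -0.16 (camera adjusted p = 0.0247; adjusted p = 0.853 with an estimated correlation). Under cyclic loess the medians from day 3 to day 5 were -0.46 for OTP and -0.29 for the plastid genes. Centred on the poly-A spike-in controls, which put the median of all probe sets at -0.545, they were -1.02 and -0.88. The ATG, OTP and plastid groups were picked for description from all families called. The others called from day 3 to day 4 were IQD (median -0.15, 0 of 15 genes past the threshold, adjusted p = 0.041), NAD (-0.285, 0 of 8, adjusted p = 0.0329) and TBL (-0.09, 1 of 22 fallen, adjusted p = 0.0329), with adjusted p = 0.853 for each under an estimated correlation. The last was TRM, lower from day 3 to day 5 with 5 of 15 fallen (adjusted p = 0.0499; adjusted p = 0.579 with an estimated correlation).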
